A study of Mus musculus with 12 samples.

How the data were processed

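Total RNA from liver, cortex and cerebellum of 1 adult mouse of the NMR-1 strain was measured on MG_U74Av2 arrays, an oligonucleotide array of mouse transcripts made by Affymetrix. Per the labels, the RNA of a tissue was handled in either of 2 ways. The standard protocol, called 1X here, started from 5 µg and used a single linear amplification, an in vitro transcription step that copies RNA in proportion to its amount. The modified procedure, called 3X here, started from 1 ng and used 3 linear amplifications with a commercial kit for small samples. Input, kit and number of amplifications changed together, so none of them was tested alone. Each tissue had 1 array at 1X and 3 technical replicates at 3X, which gives 12 arrays in 6 groups. All arrays came from the same animal, so p-values measure only the spread between these arrays and say nothing about other mice.

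The deposited values are log2 signals per probe set, made by the authors with RMA. This method corrects the background, brings the probe distributions of the arrays together by quantile normalization and summarises the probes of a set, per the submitters' processing notes. The RMA version, the log base and whether all 12 arrays entered a single run are not given in the sources used here. The base was taken from the values: the highest was 14.46, above the natural logarithm of the largest 16-bit scanner value (11.09). The medians of the 12 arrays lay between 3.45 and 3.48. RMA uses perfect-match probes and gives no detection call, so dim signals cannot be told from background on a per-array basis and a difference against a dim signal is no measured ratio of RNA, and 19 values in 8 probe sets were below 0. For arrays, depth has no count, and the number of arrays limits the precision.

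The table held 12488 probe sets. The 66 control probe sets of the manufacturer were kept out of the tests, which left 12422. Of these, 10833 carried 1 gene symbol in the platform annotation, 396 carried several and 1193 carried none. Genes were named only from probe sets with 1 symbol. Gene identifiers of 10817 of them were found in a RefSeq gene table of assembly GRCm38.p6, used only for names, and no symbol changed. The symbols stood for 8251 genes, 2073 of them with several probe sets. A further property used below is the suffix of a probe set, which marks probes shared with related transcripts or less specific probes and was carried by 2808 of those tested. No pair of arrays held identical values.

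Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes, two-sided) with Benjamini-Hochberg adjustment over the 12422 probe sets. A probe set was called at an adjusted p under 0.05, and a second count also asked for a difference of at least 2-fold. Liver was set against the mean of cortex and cerebellum, and cortex against cerebellum, in a fit of the 9 3X arrays that shared a single estimate of the spread. The effect of amplification was the coefficient of 3X minus 1X in an additive model with tissue over all 12 arrays. Its dependence on tissue was a moderated F test of the interaction over 6 group means, in which the lone 1X array of a tissue was assumed to vary like the 3X replicates. The correlation of 1X and 3X tissue differences was described without a test, because 1X had no replicates. Control probe sets were tested by exact permutation of the place of the 1X array within each tissue, 64 placings in all, so that the smallest p was 0.0156.

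Gene lists for 25 cell types, pathways and transcript classes, written from textbook knowledge, were tested with limma's camera at a preset correlation of 0.01 and with an estimated correlation. For counts of list members, the probe set with the highest mean represented a gene. These lists, the tests, the alternatives and the rule for the genes to be named were fixed before the data were examined. Under that rule, each tissue comparison gave the 12 highest and 12 lowest genes among those called with no overlap between the arrays compared. The amplification effect gave 12 in each direction whose 1X array lay outside the 3X range on the same side in all tissues. The tissue dependence gave the 6 with the largest F. Up to 4 genes with opposite signs at 1X and 3X were taken per pair of tissues, and up to 4 members per list by the size of their difference. The symbol's probe set with the largest difference was used. A kidney list of 82 genes was written later, after the cortex and cerebellum genes had been seen, and is marked as such.

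Alternatives were quantile normalization or median centring of the arrays, probe sets above the median level, probe sets without a suffix, a mean value per gene, eBayes with trend and robust settings, a replicate block, other sets of arrays in the fit and leaving out each array. The scripts were tested on simulated arrays with 200 changed probe sets. In the fit of liver against brain, 50% of the changes of 0.5 on the log2 scale were recovered, 92% of those of 1 and 99% of those of 2. For the interaction these shares were 0%, 46.5% and 90.5%. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for descriptions and plots. No genome sequence was used, so no positions are given.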

Results

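Expression was profiled in liver, cortex and cerebellum of a single adult NMR-1 mouse on 12 arrays. A standard protocol with a single linear amplification of 5 µg RNA (1X) had 1 array per tissue. The procedure it was compared with, 1 ng RNA amplified linearly 3 times (3X), had 3 technical replicates per tissue. Signals are log2 values of 12422 probe sets, and differences are given on the log2 scale with the standard error (SE) from limma. The 3X replicates of a tissue resembled each other closely. Across probe sets, which are not independent replicates, Pearson's r between 3X arrays of the same tissue was 0.977 to 0.994 in 9 pairs, against 0.893 to 0.928 in the 9 pairs of a 3X array with the 1X array of its tissue. Between 3X arrays of different tissues it was 0.983 to 0.989 for cortex with cerebellum and 0.903 to 0.930 for liver with a brain region, so that a 3X liver array resembled a 3X brain array about as closely as its own 1X array. The median SD of the 3 arrays was 0.13 in liver, 0.11 in cortex and 0.10 in cerebellum on the log2 scale. Liver replicate 3 lay closer to the 1X liver array (r = 0.928) than replicates 1 and 2 (0.894 and 0.893).

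Genes of the secretory and metabolic functions of the liver were far higher in liver than in the brain regions on the 3X arrays. Plasminogen (Plg), the precursor of the clot-dissolving protease plasmin, was higher by 8.76 ± 0.25 (SE, 3 liver against 6 brain arrays; limma adjusted p = 1.8e-09). Its mean signals in cortex and cerebellum, 2.52 and 2.27, were dim, so no fold is given. Albumin (Alb) was higher by 7.32 ± 0.22, the fatty acid-binding protein Fabp1 by 7.39 ± 0.23 and the HDL apolipoprotein Apoa1 by 6.87 ± 0.14. In the opposite direction, Ptgds, which makes prostaglandin D2 in the brain, was lower in liver by -7.13 ± 0.40, and dynamin 1 (Dnm1), which acts in synaptic vesicle recycling, by -6.32 ± 0.28. The fit shares a single spread over the tissues, but the liver arrays varied more for these genes. The liver SD was 0.719 for Plg, 0.696 for Fabp1, 0.664 for Alb and 1.267 for Ptgds, against 0.235 or less in the brain regions. Their SE and p-values therefore understate the spread in liver. All 4 plasma and lipid genes and both brain genes were past the threshold without overlap between liver and brain arrays, as the rule for naming required. Of all 12422 probe sets, 2129 met both conditions.

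In total 2537 of 12422 probe sets were called between liver and the mean of both brain regions, 1015 higher and 1522 lower in liver, and 678 of them differed at least 2-fold. The remaining genes with the largest positive differences were the antitrypsins Serpina1b (6.83 ± 0.13) and Serpina1c (6.75 ± 0.12), the heme-binding hemopexin (Hpx, 6.81 ± 0.13) and fetuin-A (Ahsg, 6.64 ± 0.12). They were followed by Bhmt of methionine metabolism (6.54 ± 0.18), the hydroxysteroid dehydrogenase Akr1c6 (6.48 ± 0.25), the carboxylesterase Ces3a (6.31 ± 0.12) and the urea cycle enzyme Otc (6.31 ± 0.17). Their limma adjusted p-values were 2.17e-08 or lower. The shared spread can understate that of liver here too, as for Akr1c6, with an SD of 0.765 in liver and 0.132 in cortex. The remaining genes with the largest negative differences were chromogranin B (Chgb, -5.82 ± 0.16), Basp1 of growing axons (-5.35 ± 0.13), the tubulin Tuba1a (-5.13 ± 0.23) and tau (Mapt, -4.86 ± 0.17). They were followed by the G protein subunit Gnao1 (-4.83 ± 0.14), carboxypeptidase E (Cpe, -4.70 ± 0.25), the astrocytic connexin 43 (Gja1, -4.66 ± 0.22) and reticulon 1 (Rtn1, -4.51 ± 0.20). The neurofilament protein alpha-internexin (Ina) stood at -4.46 ± 0.13 and the RNA-binding protein Celf4 at -4.42 ± 0.11. The 3X liver means of Cpe and Gja1 were negative, at -0.754 and -1.685. Gja1 was dim in cortex (2.651) and cerebellum (3.295) too, below the array medians. Their differences are therefore no measured ratios of RNA. The same holds for others here against a dim signal, such as Basp1 in liver (0.829) or Hpx in cortex (2.349). The probe sets of Cpe and Gja1, like some others named here, carry a suffix for shared or less specific probes.

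By group, 40 of 44 measured genes for plasma proteins and coagulation were called higher in liver and none lower (43 adjusted over the list alone; camera adjusted p = 3.27e-43). Lipid transport and metabolism had 20 of 27 higher, with Apoa2 at 5.70 ± 0.07 and Apob at 5.47 ± 0.25 (22 adjusted over the list alone; camera adjusted p = 1.17e-20). Amino acid metabolism and the urea cycle had 20 of 23, with Cps1 at 4.69 ± 0.26 and Arg1 at 4.47 ± 0.12 (20 adjusted over the list alone; camera adjusted p = 4.84e-22). Xenobiotic and bile acid metabolism had 32 of 40, with Mgst1 at 5.07 ± 0.18 and Cyp3a11 at 4.66 ± 0.36 (36 adjusted over the list alone; camera adjusted p = 5.17e-29). Glucose and glycogen metabolism had 7 of 13, led by Fbp1 of gluconeogenesis at 5.00 ± 0.19 and Igf1 at 4.88 ± 0.19 (7 higher and 1 lower adjusted over the list alone; camera adjusted p = 6.13e-06). Of 12 liver transcription factors 4 were higher, among them Cebpa (0.89 ± 0.08), Nr1h3 (0.88 ± 0.08) and Onecut1 (0.32 ± 0.07), while Foxa2 at 0.27 ± 0.11 did not pass (adjusted p = 0.124). That list had 5 adjusted over the list alone and a camera adjusted p of 0.000493.

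Pan-neuronal and synaptic genes were lower in liver for 44 of 65 members and higher for none (47 adjusted over the list alone; camera adjusted p = 1.42e-24). Astrocyte genes were lower for 14 of 26 (14 adjusted over the list alone; camera adjusted p = 3.65e-05), including the glycolytic Aldoc (-2.70 ± 0.08) and cystatin C (Cst3, -2.63 ± 0.13), but apolipoprotein E (Apoe), which the liver also makes, was higher by 2.07 ± 0.11. Of 18 housekeeping genes 9 were lower and 2 higher (9 and 2 adjusted over the list alone; camera adjusted p = 0.000493), with Aldoa at -2.81 ± 0.07 and B2m at 2.56 ± 0.22. These 3 lists and the 6 liver lists also passed with an estimated correlation, but far less strongly. The camera adjusted p was then 0.0494 for amino acid metabolism, 0.0444 for astrocyte genes and 0.0277 for each of the others. For plasma protein genes the estimated correlation was 0.331, against the preset 0.01. Forebrain markers were lower for 14 of 40 (15 adjusted over the list alone; camera adjusted p = 0.000303, but adjusted p = 0.234 with an estimated correlation), and cerebellar markers for 10 of 46 (10 adjusted over the list alone; camera adjusted p = 0.00662, but adjusted p = 0.130 with an estimated correlation). Nuclear genes of oxidative phosphorylation were lower for 13 of 75 (13 adjusted over the list alone; camera adjusted p = 0.0221, but adjusted p = 0.422 with an estimated correlation), with Cox6c at -1.77 ± 0.42. The other 13 lists did not pass, with adjusted p from 0.0540 to 0.716. Called separately against each region, 2082 probe sets differed between liver and cortex (825 higher, 1257 lower in liver) and 2059 between liver and cerebellum (792 higher, 1267 lower). A single alternative chosen after seeing the data, a call in the same direction against each region, left 1549.

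Cortex and cerebellum differed in fewer genes, and genes of their neuron types were among those named. Kalrn, a regulator of dendritic spines, was higher in cortex by 3.92 ± 0.14 (SE, 3 against 3 arrays; limma adjusted p = 3.26e-07), and the kinase Ptk2b by 3.08 ± 0.16 (8.47-fold; 5.46e-06). Gabra6, the GABA receptor subunit of cerebellar granule cells, was lower in cortex by -2.33 ± 0.15 (3.19e-05), and Zic1, a transcription factor of that lineage, by -1.94 ± 0.13 (4.97e-05). The most negative difference of all belonged to Napsa, an aspartic protease known from lung and kidney, at -3.43 ± 0.12 (3.26e-07).

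In all, 132 probe sets were called, 54 higher and 78 lower in cortex, 52 of them at least 2-fold. Further genes higher in cortex were the opioid precursor Penk (1.87 ± 0.20), the postsynaptic protein neurogranin (Nrgn, 1.77 ± 0.13), the calcineurin subunits Ppp3r1 (1.76 ± 0.18) and Ppp3ca (1.35 ± 0.19), Olfm1 (1.73 ± 0.18) and Plxnd1 (1.55 ± 0.15). The transcription factor Fezf2 of deep-layer neurons had a signal of 3.44 ± 0.27 (SD, n = 3) in cortex and 1.94 ± 0.13 in cerebellum. Mef2c (1.43 ± 0.14), Sowaha (1.38 ± 0.13) and the forebrain adhesion molecule Icam5 (1.37 ± 0.15) were higher too. Their limma adjusted p-values lay between 7.75e-05 and 0.00550. The other 3 Mef2c probe sets were not called, nor was their mean with this one, at 0.40 (adjusted p = 0.0824). With all 12 arrays in an additive fit, Penk (1.96 ± 0.40) and Ppp3ca (1.26 ± 0.26) were no longer called. Further genes higher in cerebellum were the transcription factor Neurod1 (-1.86 ± 0.21), Septin4 (-1.90 ± 0.08), the myelin gene Mobp (-1.77 ± 0.19) and Smarcd2 (-1.91 ± 0.25). With them were 5 genes that are best known outside the brain, namely Fbp1 (-2.59 ± 0.22), Hsd3b2 (-2.54 ± 0.25), Hao2 (-1.97 ± 0.25), kininogen (Kng1, -1.46 ± 0.16) and the kallikrein Klk1b5 (-1.44 ± 0.17). The 1X arrays gave the same sign for all 24 of these genes, with Napsa at -1.81 and Fbp1 at -2.18.

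Forebrain markers were higher in cortex for 10 of 40 genes and lower for none (16 adjusted over the list alone; camera adjusted p = 7.91e-22), and cerebellar markers were higher in cerebellum for 8 of 46 (8 adjusted over the list alone; camera adjusted p = 6.26e-10), with Pvalb at -1.17 ± 0.14. Both also passed with an estimated correlation (camera adjusted p = 0.0464 for each). Oligodendrocyte and myelin genes had a call for 1 of 18 members at the probe set with the highest signal, Mbp at -1.36 ± 0.13 (5 lower adjusted over the list alone; camera adjusted p = 2.74e-06, but adjusted p = 0.0748 with an estimated correlation). For Mobp that probe set was not called (adjusted p = 0.710), unlike the Mobp probe set named above. Astrocyte genes had 2 of 26 lower in cortex, Hopx (-1.04 ± 0.17) and Aldoc (-0.78 ± 0.09), with 8 lower and 2 higher adjusted over the list alone (camera adjusted p = 0.00165, but adjusted p = 0.160 with an estimated correlation). Striatal genes had 2 of 9 higher, Penk and Pde1b (0.72 ± 0.10; 2 adjusted over the list alone; camera adjusted p = 0.000156, but adjusted p = 0.0523 with an estimated correlation). Pan-neuronal genes had 4 higher, among them Gria2 (0.98 ± 0.17), and 2 lower, the neurofilament genes Nefh (-1.16 ± 0.11) and Nefm (-1.13 ± 0.15), with 14 and 5 adjusted over the list alone (camera adjusted p = 0.0143, but adjusted p = 0.604 with an estimated correlation). The other 19 lists did not pass.

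Kidney genes moved with the cerebellum label. A kidney list was written after the genes above had been seen. It was tested without them and without members of the forebrain, cerebellar and choroid plexus lists, 10 genes in all. Of its 44 measured genes 8 were called higher in cerebellum and none in cortex (12 and 0 adjusted over the list alone). The median difference was -0.15 at 3X and -0.25 at 1X (camera p = 3.26e-13, and p = 0.00276 with an estimated correlation). On the 1X arrays, the kidney androgen-regulated protein gene Kap had a signal of 8.66 in cerebellum against 4.92 in cortex and 4.66 in liver, and Miox, a proximal tubule enzyme, 8.51 against 4.67 and 4.38. At 3X the difference was -1.04 ± 0.11 for Kap, -0.86 ± 0.17 for Miox, -0.88 ± 0.09 for uromodulin (Umod) and -0.95 ± 0.10 for the phosphate transporter Slc34a1, with limma adjusted p from 0.000639 to 0.0472. The number of calls between cortex and cerebellum was 250 without liver replicate 3, 82 without cerebellum replicate 2, 86 without cerebellum replicate 3 and 88 without cortex replicate 1 or 3. It was 262 when the spread came from the 6 cortex and cerebellum arrays alone.

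**Figure D1:**
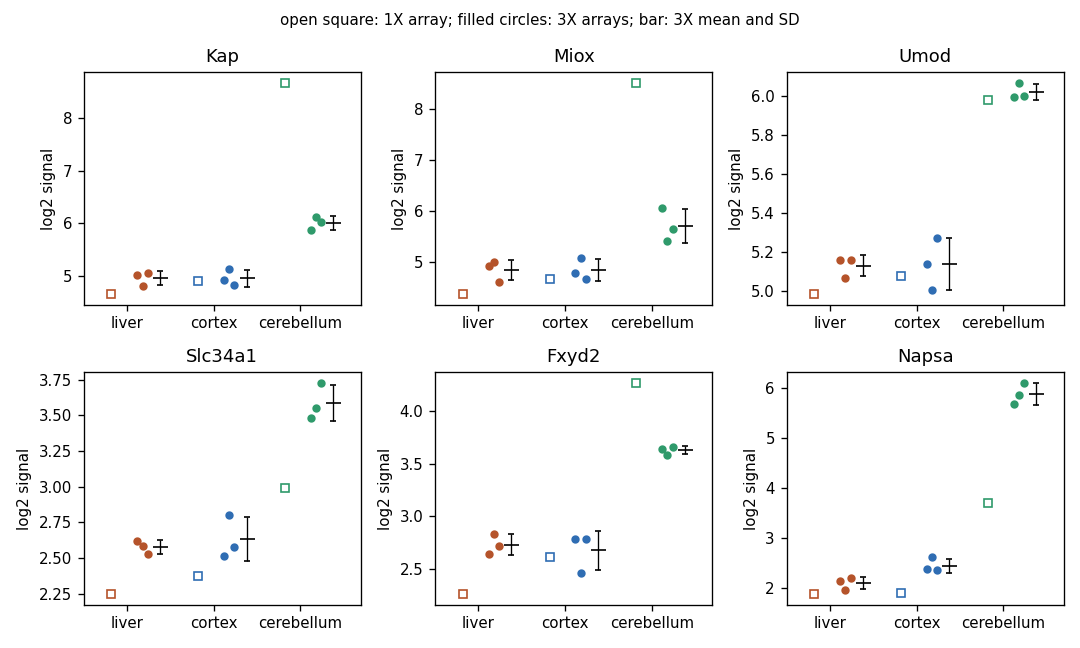
Log2 signal of 6 kidney genes per array in the 3 tissues, with the 1X array as an open square, the 3X arrays as filled circles and the 3X mean with its SD as a bar; axes do not start at 0. For Kap the 1X cerebellum array stands at 8.66 and the 1X cortex array at 4.92, and for each of the 6 genes all cerebellum arrays lie above all cortex arrays.

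The 3X procedure changed the signal of many genes in the same way in all 3 tissues. It differed from 1X in RNA input and kit as well as in the number of amplifications, so the effect is that of the procedure as a whole. The 9 sense probe sets of bacterial controls added at hybridization also rose, by 1.02 to 2.58. A difference that arose at or after hybridization therefore cannot be separated from the effect. Atp5l, a small subunit of ATP synthase, fell by 5.46 ± 0.09 (SE; 9 3X against 3 1X arrays; 44.0-fold; limma adjusted p = 5.63e-11), from between 11.3 and 11.8 at 1X to between 6.05 and 6.26 at 3X. The cytoskeletal actin Actg1 fell by 4.32 ± 0.29, the acyl-CoA-binding protein gene Dbi by 4.04 ± 0.36 and Hint1 by 4.04 ± 0.16. The largest rise among the named genes was that of a probe set for the aldehyde dehydrogenase Aldh2 (3.36 ± 0.22; 1.22e-06), followed by Faap20 (3.12 ± 0.26), S100a13 (3.05 ± 0.15) and Fam3c (2.86 ± 0.29). In cortex and cerebellum this Aldh2 probe set stood at -1.541 and -1.165 at 1X and at 2.272 and 2.669 at 3X. Its rise there is no measured ratio of RNA. The probe sets of these genes, and those of Uqcrc2, Gstm5 and Akirin2 below, carry a suffix for shared or less specific probes.

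Of 12422 probe sets, 7073 were called, 4654 higher and 2419 lower at 3X. Of the 1048 that also changed at least 2-fold, 274 were higher and 774 lower. The median of all probe sets was 0.12 higher at 3X as deposited, 0.08 after quantile normalization and 0.13 after median centring. Small rises are to be read against that shift. Further rises were found for Uqcrc2 of respiratory complex III (2.70 ± 0.17), Imp4 (2.68 ± 0.23), the glutathione transferase Gstm5 (2.65 ± 0.16) and the kinase subunit Csnk2a1 (2.63 ± 0.32). Akirin2 (2.58 ± 0.08), Grhpr (2.55 ± 0.12) and Txndc9 (2.49 ± 0.20) rose as well, and Pkp2 rose in liver from 2.22 to 5.36 ± 0.09 (SD, n = 3). Further falls were found for the dynein light chain Dynll2 (-4.02 ± 0.27), Septin7 (-3.93 ± 0.32), the ATP synthase subunit Atp5e (-3.90 ± 0.16), the tubulin Tuba1c (-3.79 ± 0.31) and the ribosomal protein Rps4x (-3.68 ± 0.35). They were followed by Arf1 of vesicle traffic (-3.59 ± 0.15), Uqcrh (-3.54 ± 0.10) and Elob (-3.40 ± 0.24). The limma adjusted p of these 16 genes was 7.65e-05 or lower, and all 24 named genes kept their direction under both other scalings. Several named genes had another probe set called in the opposite direction. Aldh2 had a further probe set that fell by 1.40, and its mean over probe sets, at 0.42, was not called (adjusted p = 0.225). Other probe sets fell by 0.52 for S100a13, by 0.55 for Fam3c, by 0.65 for Gstm5 and by 0.53 for Csnk2a1. Among the falls, other probe sets rose by 0.38 for Atp5l, by 0.49 for Dynll2 and by up to 0.36 for Rps4x. With the 3 tissues as units, 4690 probe sets were called.

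Housekeeping genes fell for 11 of 18 members and rose for 3 (11 and 3 adjusted over the list alone; camera adjusted p = 0.0136, but adjusted p = 0.0843 with an estimated correlation). Among them were the glycolytic Tpi1 (-3.11 ± 0.16) and Ldha (-2.18 ± 0.23), the elongation factor Eef2 (-2.62 ± 0.15) and Sdha (-2.04 ± 0.12). Proteasome genes fell for 25 of 46 and rose for 13 (26 and 13 adjusted over the list alone; camera adjusted p = 7.89e-05, but adjusted p = 0.385 with an estimated correlation), with Psmb5 at -2.51 ± 0.09 and Psma4 at -2.38 ± 0.21. Chaperone genes fell for 22 of 55 and rose for 11 (22 and 11 adjusted over the list alone; camera adjusted p = 0.0229, but adjusted p = 0.0843 with an estimated correlation), with Hsp90b1 at -2.89 ± 0.27 and Hspa8 at -2.68 ± 0.22. Oxidative phosphorylation genes fell for 31 of 75 and rose for 19 (32 and 20 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.0679), though it did with 1 probe set per gene (camera adjusted p = 0.00223; 0.983 with all and an estimated correlation). Cytosolic ribosomal protein genes went both ways, 11 down and 14 up of 35 (11 and 14 adjusted over the list alone; camera adjusted p = 0.945), from Rps4x to a rise of 2.62 ± 0.13 for a probe set of Rps28, of which another probe set fell by 2.70. Long transcripts also went both ways, 10 down and 15 up of 40 (10 and 16 adjusted over the list alone; camera adjusted p = 0.945), with Sptan1 at -2.09 ± 0.26 and Plec at 1.38 ± 0.10. In all, 22 lists did not pass. Among them, astrocyte genes (8 down and 3 up of 26) had a camera adjusted p of 0.0731. It was 0.0142 with 1 probe set per gene and 0.766 with an estimated correlation.

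The manufacturer's control probe sets measure different parts of a transcript. The 3' minus 5' difference of beta-actin (Actb) rose from between -0.93 and -0.52 at 1X to 1.28 ± 0.34 (SD, n = 3) in liver, 2.86 ± 0.12 in cortex and 2.91 ± 0.17 in cerebellum, a mean change of 3.08 (exact permutation p = 0.0156, the smallest possible; 0.0195 after adjustment over 5 transcripts). For Gapdh the mean change was 1.25 (exact p = 0.0156), for 18S ribosomal RNA -1.40 (exact p = 0.0156), for pyruvate carboxylase (Pcx) -0.60 (exact p = 0.0156) and for the transferrin receptor (Tfrc) 0.19 (exact p = 0.219). The 3' and 5' sets of Tfrc were dim, with 1X values and 3X means from 2.25 to 3.10, below the array medians. Their difference therefore cannot show whether 5' sequence was kept. The Actb 5' probe set itself fell by 4.20 and its 3' probe set by 1.12, while those of Gapdh fell by 4.05 and by 2.80. The middle probe sets fell by 4.70 for Actb and by 5.22 for Gapdh on average. Against the middle, the 3' difference changed by 3.58 for Actb and 2.42 for Gapdh (exact p = 0.0156 for each). The 18S probe sets rose at 3X, the 3' set by 7.91 on average and the 5' set by 9.31. At 1X the 5' set held the lowest value of each array (-4.62 in liver, -4.63 in cortex, -4.82 in cerebellum). Its rise and the 18S difference are therefore no measured ratios of RNA. After quantile normalization the 18S difference turned to 2.22, and the Pcx difference was -0.27 against the first of 2 middle probe sets (exact p = 0.0781). Against the second, an alternative chosen after seeing the data, it turned to 0.52 (exact p = 0.0156).

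**Figure D2:**
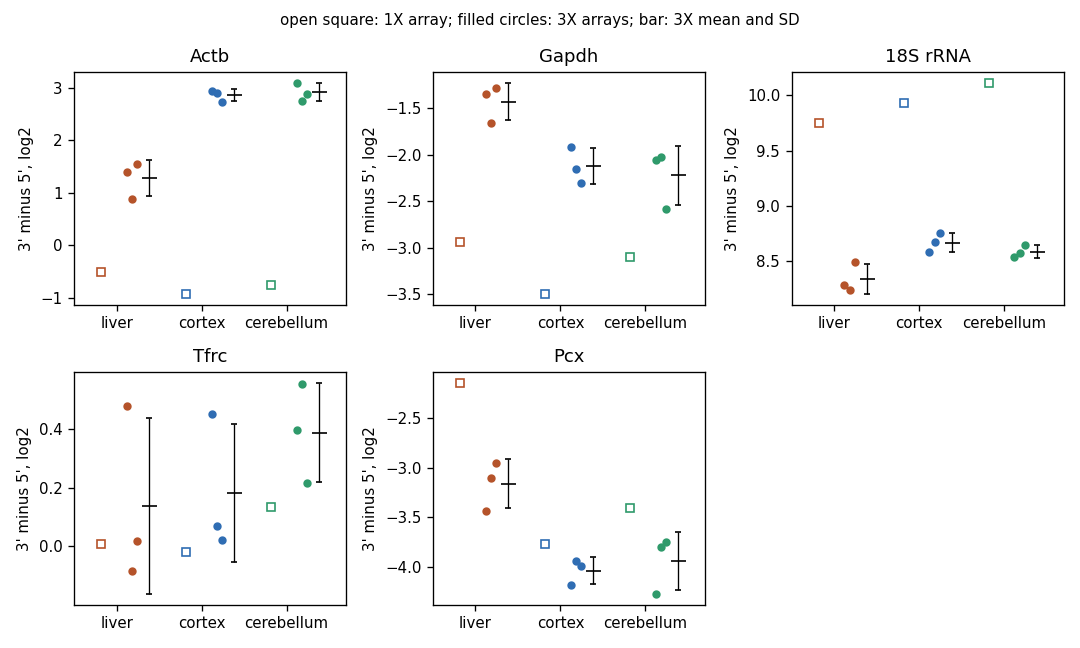
Difference between the 3' and 5' control probe sets of 5 transcripts on the log2 scale, per array and tissue, with 1X arrays as open squares, 3X arrays as filled circles and bars for the 3X mean and SD; axes do not start at 0. For Actb the 1X arrays lie between -0.93 and -0.52 and the 3X means between 1.28 and 2.91.

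For some transcripts the change from 1X to 3X differed between tissues. Those named were transcripts with high signal in a single tissue or in the brain at 1X that came close to the other tissues at 3X. Hepcidin (Hamp), the iron-regulating hormone of the liver, fell by 6.24 in liver, from 8.92 to 2.68 ± 0.18 (SD, n = 3), and changed by 0.13 in cortex and 0.23 in cerebellum. The plasma protein orosomucoid 1 (Orm1) fell by 4.81 in liver, the tryptophan-degrading enzyme Tdo2 by 3.78 and the methionine sulfoxide reductase Msrb1 by 3.39. In the opposite pattern, the neuronal ubiquitin hydrolase Uchl1 fell by 3.71 in cortex and by 3.36 in cerebellum and changed by 0.46 in liver, and the myelin gene Mobp fell by 4.46 in cerebellum and by 2.52 in cortex at a probe set other than that named above. The limma adjusted p of the interaction was 3.77e-06 or lower for these 6 genes. On the 1X arrays Hamp stood at 2.30 in cortex and 2.12 in cerebellum, Orm1 at 2.12 and 1.96, and this Mobp probe set at 3.05 in liver. Signals this dim had little room to fall, so the interaction does not show that amplification acted differently there. For the other genes named, background could not be told from signal.

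**Figure D3:**
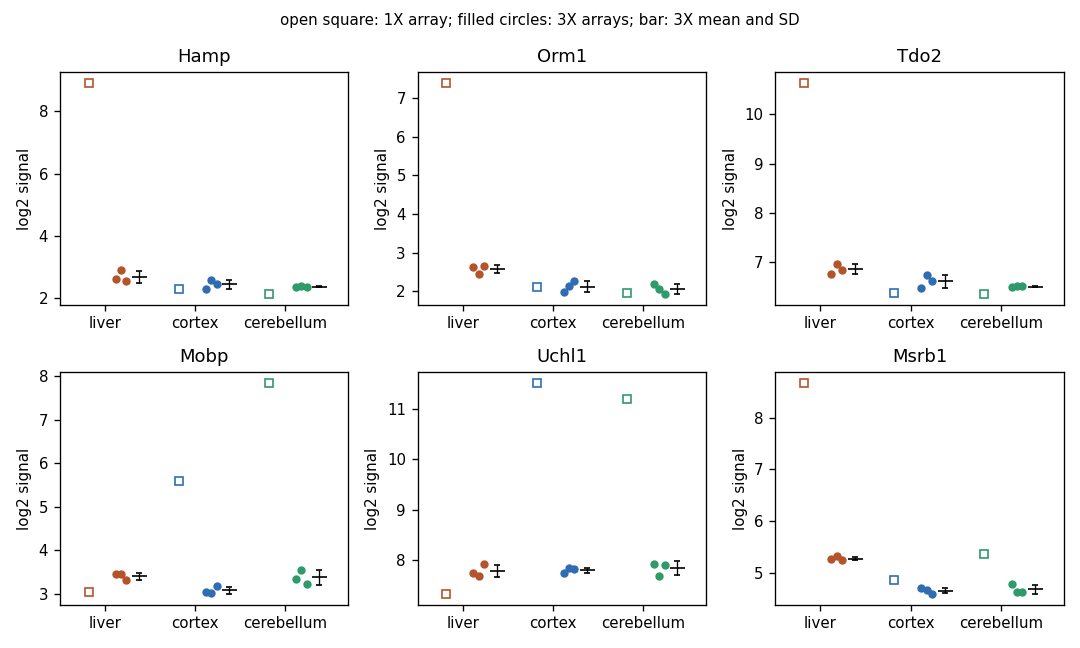
Log2 signal per array of the 6 genes with the strongest tissue dependence of the amplification effect, with 1X arrays as open squares, 3X arrays as filled circles and bars for the 3X mean and SD; axes do not start at 0. Hamp stands at 8.92 on the 1X liver array and at a mean of 2.68 on the 3X liver arrays, near the 3X means of cortex (2.43) and cerebellum (2.36).

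The interaction passed for 1294 probe sets, and rests on a single 1X array per tissue. Across probe sets, the amplification effect correlated between cortex and cerebellum with r = 0.942 (Spearman's rho = 0.905), between liver and cerebellum with r = 0.594 (0.639) and between liver and cortex with r = 0.559 (0.606). Without the liver 1X array, whose tissue then drops out of the test, 44 probe sets passed, against 1255 without the cortex and 1322 without the cerebellum 1X array. Without the liver 1X array the interaction was no longer called for Hamp, Orm1, Tdo2, Uchl1 and Msrb1.

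Most probe sets at least 2-fold apart between tissues at 1X kept their direction at 3X, but their differences were smaller. The share still at least 2-fold apart in that direction was 33.3% for liver minus cortex, 32.5% for liver minus cerebellum and 24.9% for cortex minus cerebellum. The median ratio of the 3X to the 1X difference was 0.31, 0.30 and 0.33 among them. These probe sets were picked on single 1X arrays, which alone makes some shrinkage likely. Of the 1638 probe sets at least 2-fold apart between liver and the brain mean at 1X, 93.5% had the same sign at 3X and 1105 (67.5%) were called in the same direction, 3 in the opposite one. The share called rose to 85.6% of the 692 probe sets at least 4-fold apart and 97.4% of the 191 at least 16-fold apart. Plasma protein genes had a median difference of 4.88 at 1X and 1.98 at 3X, and pan-neuronal genes -2.06 and -0.64.

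Across probe sets the 3X log ratios correlated with the 1X log ratios with r = 0.786 for liver minus cortex, 0.786 for liver minus cerebellum and 0.610 for cortex minus cerebellum (Spearman's rho 0.554, 0.571 and 0.402). The SD of the 3X log ratios was 0.624, 0.615 and 0.687 of that at 1X, with the mean of 3 arrays at 3X against a single array at 1X. With single 3X arrays the ratio was 0.594 to 0.695 and 0.623 to 0.677 for the liver pairs, and 0.831 to 0.933 for cortex minus cerebellum. Between cortex and cerebellum, 181 probe sets were at least 2-fold apart at 1X, of which 172 had the same sign at 3X and 65 were called, none in the opposite direction. Some probe sets at least 2-fold apart at 1X were called with the opposite sign at 3X. For Ptpn5, a phosphatase of striatal neurons, liver minus cortex was -1.96 at 1X and 0.44 ± 0.11 at 3X, and liver minus cerebellum -1.04 and 0.57 ± 0.11. Of 2 probe sets of Actb, the first gave 1.70 and -0.39 ± 0.11 against cortex and the second 1.21 and -0.53 ± 0.14 against cerebellum. The same was found for Arhgef25 against cortex (-1.25 and 0.36 ± 0.10) and for Abca2 against cerebellum (-1.12 and 0.47 ± 0.13). These probe sets were picked for their opposite signs, and all of them rest on the single 1X liver array. The 3', middle and 5' control probe sets of Actb did not reverse. Their signals were lower in liver than in either brain region at 1X and at 3X. The middle set stood at 10.55 in liver and 12.09 in cortex at 1X, and at 5.79 and 7.67 at 3X.

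**Figure D4:**
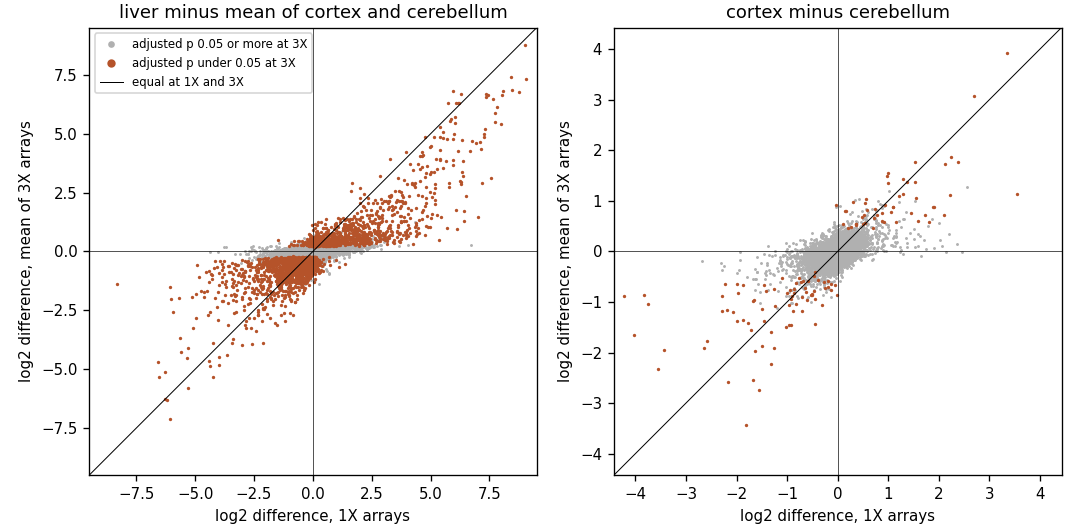
Log2 differences between tissues at 3X (mean of the replicates, vertical axis) against those at 1X (horizontal axis) for 12422 probe sets, with liver minus the brain mean on the left and cortex minus cerebellum on the right; coloured points were called at 3X and the diagonal marks equality. Most points far from 0 at 1X lie between the diagonal and the horizontal axis, as the median of plasma protein genes does (4.88 at 1X, 1.98 at 3X).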

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

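The tests of the explanation by shared probes and of other placings of the 1X arrays were chosen after the results had been seen; the tests of whole transcripts and of signal level were written before their values were known. The amplification effect differed between tissues by a test of the interaction for 1294 probe sets. Among the genes named for it, the range of the effect over the 3 tissues was 6.48 on the log2 scale for Hamp, 4.91 for Orm1, 4.01 for Tdo2, 4.82 for Mobp, 4.17 for Uchl1 and 3.18 for Msrb1. Of the 24 genes named for their shared amplification effect, 7 also differed in its size between tissues: Dbi with a range of 2.69, Septin7 with 2.01, Tuba1c with 1.98, Actg1 with 1.95, Dynll2 with 1.86, Aldh2 with 1.41 and Arf1 with 0.97 (limma adjusted p from 3.77e-05 to 0.0426), all moving the same way in the 3 tissues. With the shared effect taken off first, 1 of the 64 placings of the 1X label within tissues gave as many calls as the real 1294, the real one. Every other placing left a real 1X array among those taken as 3X, which widens the spread and lowers the count. The placings therefore do not exclude chance. The highest of the others gave 470 and kept the real 1X arrays of liver and cortex. A 1X array that varied more than the 3X replicates would give such a result too, which was not tested. For the shared effect, 1 of the 64 placings gave as many as the real 7073, and the highest of the others gave 0, with the same limit.

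A signal also appeared in control probe sets that were kept out of the limma tests. The array carries probe sets against the opposite strand of Actb and Gapdh, and all 6 of them were higher at 3X, with a median change of 2.10 and a range from 0.95 to 2.91 on the log2 scale. The 9 opposite-strand sets of bacterial controls were higher too, by a median of 0.59. The 9 sense sets of the bacterial controls added at hybridization rose by a median of 2.44, and the 15 sets for Bacillus genes by 0.25.

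The effect of amplification was uneven between probe sets, from -5.46 for Atp5l to 3.36 for Aldh2. If it belonged to the whole transcript, probe sets of the same gene would share it. Their intraclass correlation was 0.0762 (bootstrap 95% interval 0.0244 to 0.135, 2073 genes), against 0.595 for the liver minus brain difference at 1X. Over all probe sets this argues against a transcript-wide property as the main source. Sets with a suffix were included and the correlation was not computed without them, so a shared effect among more specific sets stays open. A trend with signal level held 4.05% of the variance of the effect, which argues against the trend as the main source too. Falls of at least 2-fold still went from 4 among the 2485 dimmest probe sets to 295 among the 2485 brightest, so a part of level in the falls stays open. Of the 274 probe sets raised at least 2-fold, 63.9% carried a suffix for shared or less specific probes, against 22.6% of all tested and 14.3% of the 774 lowered ones, so cross-hybridisation may account for part of the rises and remains open, and the falls need another source. No biological explanation was tested, because the RNA of a tissue was the same in both protocols.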

How the results depend on the processing

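Each alternative was set beside the result it tests, and all but 4 were fixed before the data were examined. Of 1436 fits of the named genes, 1427 gave the same call, 9 no longer passed and none was reversed. Of 225 tests of gene lists, 188 gave the same result, 21 passed where the first test did not, 14 no longer passed and 2 had the opposite direction. Those 2 were for amplification with fry, which tests the members against 0 and not against all other genes: ribosomal proteins (adjusted p = 0.0423) and long transcripts (0.0115). Cerebellar markers between liver and brain had an adjusted p of 0.0663 with 1 probe set per gene.

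Restriction to probe sets above the median level gave 1607 calls for liver against brain, 1347 against cortex, 1341 against cerebellum, 3685 for amplification and 804 for its tissue dependence. With a difference of at least 2-fold, the counts were 678, 674, 661 and 1048, and 52 for cortex against cerebellum. For amplification, a mean value per gene gave 4586 calls and tissues as units 4690. With the spread from the arrays compared alone, cortex against cerebellum gave 262. A call against each brain region, chosen after seeing the data, left 1549 for liver, and the brain regions alone, also chosen then, gave 7125 for amplification. Leaving out 1 array moved the cortex and cerebellum count between 82 (without cerebellum 3X replicate 2) and 250 (without liver 3X replicate 3), and the tissue dependence between 44 (without the liver 1X array) and 1814 (without liver 3X replicate 3). Mef2c, as a mean per gene, was at 0.40 between cortex and cerebellum (limma adjusted p = 0.0824). In the additive fit of all 12 arrays, Penk was at 1.96 and Ppp3ca at 1.26 (limma adjusted p = 0.0502 and 0.0587). Oxidative phosphorylation genes passed for amplification with fry (adjusted p = 0.000998).

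With single 3X arrays, r between 1X and 3X log ratios was 0.714 and 0.717 for liver minus cortex and 0.721 and 0.710 for liver minus cerebellum (numbers 1 and 2), and 0.820 and 0.817 with number 3. For cortex minus cerebellum it was 0.451, 0.512 and 0.474 (numbers 1 to 3), and 0.641 with a mean per gene. For liver minus the brain mean, chosen after seeing the data, it was 0.790. The amplification effect correlated between liver and cortex with 0.582 after quantile normalization, and with 0.541 to 0.566 on leaving out a replicate number. Between liver and cerebellum these values were 0.619 and 0.574 to 0.603. Between cortex and cerebellum they were 0.950 above the median level and 0.930 to 0.940 on leaving out a replicate number. Quantile normalization turned the 18S control difference to 2.22, and Pcx was at -0.27 against its first middle probe set (exact p = 0.0781) and turned to 0.52 against its second (exact p = 0.0156; chosen after seeing the data).

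With a replicate block, the counts were 2729 for liver against brain, 170 for cortex against cerebellum, 7272 for amplification, 1412 for its tissue dependence, 2277 for liver against cortex and 2225 for liver against cerebellum. The labels number the 3X samples so that the 3 tissues of a replicate number follow each other, and name no shared batch or day. After removal of tissue means, r was over 0.1 in 5 of 9 pairs with the same number (median 0.238, from -0.0991 to 0.342; number 3 from 0.294 to 0.342), and its median was -0.113 for other numbers. An array correlated best with its own number in 9 of 18 combinations, where chance gives 6, so the numbers were not taken to pair the arrays, and handling in such sets stays open.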

Other observations

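All tests of brain transcripts in liver and of other groupings of the arrays in this part were chosen after the results had been seen; both tests of kidney genes were written before the list's values were known, though after its first genes were. Some genes known from resident cells of the liver were called higher there, but their lists did not pass. Over all probe sets, 1015 of 12422 were called higher in liver and 1522 lower, so these few calls do not mark such cells as a set. The Kupffer cell genes Clec4f and Cd5l were higher in liver than in the brain regions at 3X by 1.11 ± 0.14 and 0.41 ± 0.08 (SE; limma adjusted p = 0.000174 and 0.00418), and the endothelial genes Eng and Stab1 by 1.64 ± 0.16 and 0.44 ± 0.10. Cathepsin S (Ctss), which brain microglia also make, was lower by -0.73 ± 0.12. The camera adjusted p was 0.112 for microglia and macrophage genes (4 higher, 1 lower of 30), 0.716 for endothelial genes (2 and 2 of 24) and 0.412 for cholangiocyte and stellate cell genes (1 and 0 of 16). Alpha-globin (Hba-a1), carried by red blood cells, was higher in cerebellum than in cortex by 0.99 at 3X (cortex minus cerebellum -0.99 ± 0.14, adjusted p = 0.00502), and its signals at 1X were 9.19 in cerebellum, 7.51 in cortex and 6.82 in liver.

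Probe sets of the same gene often went opposite ways after amplification: of 2073 genes with several probe sets, 330 had calls in both directions. For Ndrg2 a probe set rose by 2.03 and another fell by 2.97, for Rpl10a the values were 2.11 and -2.11, and for Atp5l 0.38 and -5.46. Actb showed the same: a probe set that fell by 4.70 on average at the middle of the transcript among the controls stood beside sets that rose by 1.65 and 1.02.

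Kidney genes formed the most unexpected pattern. The kidney list had a median cortex minus cerebellum difference of -0.15 at 3X, below all 10000 random lists matched on level, and Kap, Miox, Umod, Slc34a1 and Fxyd2 were each above the cortex in cerebellum; 17 of its 44 genes lay above the median signal on the 1X cortex array, and 2 stood in another list. On the 1X arrays the median was -0.25, again below all 10000 random lists, which argues against an origin in the 3X procedure. Of the genes seen first, Fbp1, Kng1, Hsd3b2 and Hao2 had still higher mean signals in liver at 3X (10.77, 8.37, 4.80 and 3.82), so they are not particular to kidney. Plasma protein genes as a list did not differ between cortex and cerebellum (median 0.02, camera adjusted p = 0.875). RNA from kidney cells in the RNA labelled cerebellum is a candidate source, as a hypothesis found and tested on the same arrays. Expression of the kidney genes in the cerebellum of this mouse was not tested and stays open, since there is a single RNA per tissue.

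Snap25, a synaptic gene, had a signal of 2.99 on the 1X liver array and 6.15, 7.11 and 5.26 on the 3X liver arrays, against 7.56 in the brain regions at 3X. For 15 other probe sets, at least 3 higher in brain than in liver at 1X and at 7 or more in brain at 3X, the liver signal rose by a median of 0.54, and by 0.54, 0.99 and 0.26 on the 3 arrays. The liver rise was above 9998 of 10000 lists matched on the 1X liver signal (median 0.17), but the 15 also rose in the brain regions, by a median of 0.71, and against lists matched on both it was above 83.3% (median 0.44); that match is incomplete (brain rise 0.57), so brain RNA in the liver 3X samples and the procedure's own effect on these probe sets cannot be told apart. If the whole rise came from brain RNA, these 15 would need a median share of 0.975% (upper quartile 2.75%; 0.975% and 3.38% with the 3 Ptgds probe sets counted once) and Snap25 34.1%, which argues against a single share of brain RNA as the whole cause of the Snap25 rise. Nnat alone would need 18.8%, and what else raised Snap25 stays open.

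Other groupings of the 9 3X arrays bear on the tissue counts. Of 84 groupings of 3 against 6 arrays, 1 gave as many calls as the real one (2373 in a fit of both groups). The highest of the others, cerebellum against the rest, gave 40. Every other grouping put liver and brain arrays in the same group, which widens the spread and lowers the count. The low counts therefore do not exclude chance, and the arrays are technical replicates of a single RNA per tissue. For 3 against 3 arrays there are 10 groupings, too few for a share under 0.05. The real values were 132 for cortex against cerebellum, 2082 for liver against cortex and 2059 for liver against cerebellum, and the highest of the others was 0 in each.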
